A study of Homo sapiens with 7 samples.

How the data were processed

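RNA was sequenced from 7 samples of HCC1419, an established breast cancer cell line with amplified ERBB2 (HER2). The labels give 2 untreated samples, 2 samples kept in 1 µM lapatinib for 9 days and 3 samples kept in 1 µM lapatinib for more than 70 days (called long-term below). Lapatinib is a kinase inhibitor of EGFR and HER2. Per the labels, total RNA was depleted of ribosomal RNA and made into strand-specific libraries, and cells were grown in medium conditioned by mouse embryonic fibroblasts. The long-term titles carry the codes L1P7, L1P12 and L2P6, in the order of replicates 1, 2 and 3 here. The codes are not explained in the labels. The titles also carry DTP for the 9-day and DTEP for the long-term samples. If L1 marks 1 lineage, long-term 1 and 2 are not independent, and the p-values for long-term cells count more samples than there are lineages. The labels do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

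Per the submitters' processing notes, reads were processed with Bowtie2, RSEM, SAMtools and DESeq on hg19; versions and settings are not given in the sources used here. The deposited expression table holds RSEM expected counts per gene symbol for the 7 samples. Of the deposited expected counts above 0, 69.9% were whole within 1e-06, and all were rounded to whole numbers. Of 26601 rows, 42 had no gene name and were left out, and 26559 were used, of which 19523 had at least 1 count in a library. The authors' deposited comparison table holds a mean normalised count (signal) per group, an adjusted p-value per comparison and a call per gene. Its fold change columns were not used because they hold spreadsheet errors, and 2 malformed rows and repeated symbols were left out of gene-by-gene comparison. Strand settings of the counting are not given in the sources used here, and RSEM splits reads among near-identical genes, so values of paralogs and overlapping genes are uncertain.

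Total rounded counts per library were 13059142 and 7009355 for untreated 1 and 2, 22622050 and 16478881 for 9-day 1 and 2, and 10229940, 7231486 and 5205736 for long-term 1, 2 and 3. Depth therefore differed between the groups. A count of 3, the floor used over a group for genes at 0, corresponded to between 0.133 and 0.576 CPM (counts scaled to a common library size) in single libraries. Intervals and floors cover counting error only. No pair of replicates agreed within sampling noise: chi-square over its degrees of freedom lay between 17.66 and 53.08.

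The test for each gene was edgeR 4.0.16's quasi-likelihood test (R 4.3.3; TMM normalisation, filterByExpr on the 3 groups, robust fit), with 1 coefficient per group, all 7 samples in 1 fit and 4 residual degrees of freedom. It was applied to 14472 genes in 3 comparisons, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The share of all genes called was 7.4% for 9 days against untreated, 39.1% for long-term against untreated and 23.4% for long-term against 9 days. Counts of called list members are to be read beside these shares. Standard errors are the log2 fold change divided by the square root of F, and CPM values use TMM-scaled library sizes. Exceptions are the CPM of the floor of 3 counts, of short RNAs and of TVAS5 and BC018860, which use total counts without TMM scaling. Against a group at 0 counts, folds are given as at least the ratio to the floor of 3 counts. With 1 to 3 counts they are count ratios with an exact binomial interval. Some log2 fold changes are also given for a group at 0 counts, in the full fit or with a library left out. Their size is set by the fit and was not measured. The common dispersion was 0.0587. The 27 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation and with fry. Members of a list were also counted with p adjusted over the list alone.

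The genes named were set by a rule written before the data were examined. It takes, per comparison, the 4 highest and 4 lowest log2 fold changes among called genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving out small RNA and microRNA symbols. It adds up to 4 called members of each list by adjusted p, and 14 genes regardless of outcome (ERBB2, EGFR, ERBB3, NOTCH1, NOTCH2, NOTCH3, JAG1, JAG2, HES1, HEY1, NRARP, CCND1, MKI67 and KDM5A). Of the genes it names, the text gives some of those that lead each group, and some are not reported here.

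The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For 9 days against untreated, over 14246 genes, 9% of the 2-fold and 71% of the 4-fold changes were recovered, and 5.88% of calls were false. For long-term against untreated, over 14281 genes, the shares were 20%, 81% and 10.6%. For long-term against 9 days, over 14235 genes, they were 20%, 89% and 14.8%, so the share of false calls can exceed the nominal level. Alternatives were other normalisations, DESeq2 1.42.0, limma-voom, other count filters, fits of only 2 groups, each library left out in turn, the L1 libraries summed and a replicate block. A batch term, a subset of 5 libraries and thinning to equal depth were added after seeing the data. Gene order and transcript lengths came from RefSeq and GENCODE tables of GRCh38, another build than the authors', and no coordinates are given.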

Results

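HCC1419 cells were profiled untreated (n = 2), after 9 days in 1 µM lapatinib (n = 2) and after more than 70 days in 1 µM lapatinib (n = 3). The series title links activation of the Notch pathway to lapatinib resistance. The comparisons ask which genes differ after short exposure, which differ in cells maintained in the drug, and whether the exposures differ from each other. Libraries held between 5205736 and 22622050 counts. On the first principal component, with 63.4% of the variance, the 3 long-term libraries (71.34 to 81.94) lay apart from the other 4 (-82.49 to -27.37). The second, with 15.2%, separated the untreated (32.86 and 41.05) from the 9-day libraries (-46.25 and -51.74).

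**Figure D1:**
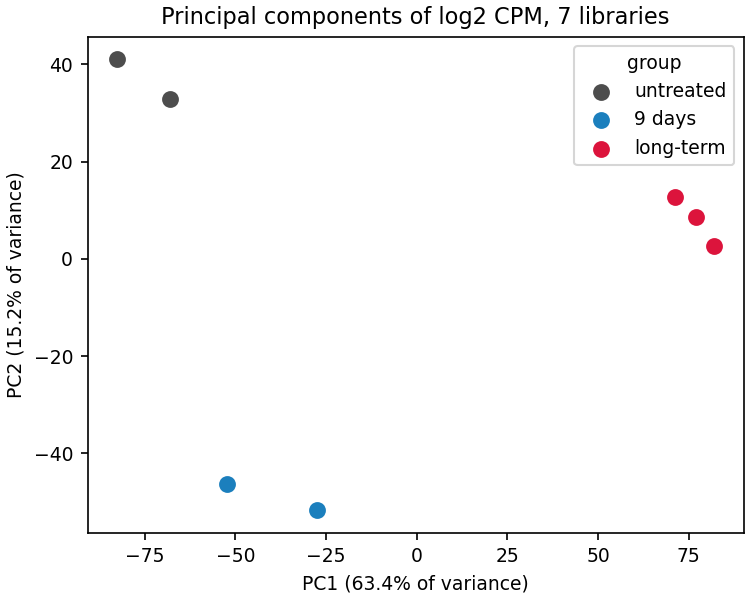
Principal components of log2 CPM over 14472 genes, with PC1 (63.4% of variance) on the x axis and PC2 (15.2%) on the y axis; each point is 1 library, coloured by group. The 3 long-term libraries sit at 71.34 to 81.94 on PC1.

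After 9 days of lapatinib, transcripts that report ERK signalling and genes of cell division were lower than in untreated cells. DUSP6, a phosphatase that acts on ERK, fell from 90.8 ± 18.9 to 1.22 ± 0.0421 CPM (SD, n = 2 each; log2 fold change -6.20, SE 0.49, adjusted p = 0.000544). The ETS factors ETV5 (-7.43, SE 0.62, adjusted p = 0.000544) and ETV4 (-6.70, SE 0.75, adjusted p = 0.0011) and the signalling inhibitor SPRY4 (-6.64, SE 0.61, adjusted p = 0.000846) fell as steeply, and these were the 4 lowest log2 fold changes. The highest were those of GPER, a G-protein-coupled estrogen receptor (6.32, SE 0.47, adjusted p = 0.000544), the mucin gene MUC19 (5.38, SE 0.81, adjusted p = 0.0104), ATG9B (4.92, SE 0.65, adjusted p = 0.00241) and the protocadherin gene PCDH19. PCDH19 had 1 count in the untreated and 63 in the 9-day libraries, a count ratio of 29.7 (interval 5.15 to 1190; adjusted p = 0.0286). Several of these values moved with single libraries. ETV4, at 0 CPM in 9-day 2, became -10.29 without 9-day 1 and -5.82 without 9-day 2. SPRY4 became -7.69 and -6.02 in that order, and ETV5 -8.07 without 9-day 1. Without untreated 1 and without untreated 2 in turn, MUC19 became 4.74 and 6.30, ATG9B 4.10 and 6.11 and PCDH19 (4.58) 3.32 and 7.27.

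All 27 measured genes of the mitosis list fell at 9 days (median log2 fold change -2.84; 27 adjusted over the list alone), among them the kinase PLK1 (-3.00), the ubiquitin-conjugating enzyme UBE2C (-3.14) and the transcription factor FOXM1 (-2.73, adjusted p = 0.000846). MKI67, a proliferation marker, fell from 144 ± 25.8 to 23.1 ± 8.45 CPM (-2.64, SE 0.31, adjusted p = 0.00149). Camera gave adjusted p = 2.13e-59 for this list, and adjusted p = 0.195 with an estimated correlation. Of 32 genes of DNA replication, 16 fell and 0 rose (29 fell adjusted over the list alone); camera gave adjusted p = 1.16e-17, and adjusted p = 0.413 with an estimated correlation. Of 15 genes of ERK transcriptional output, 7 fell and 0 rose (9 fell adjusted over the list alone; adjusted p = 7.37e-18, and adjusted p = 0.0184 with an estimated correlation). This was the 1 list of 27 whose call held with an estimated correlation.

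Metabolic lists were also lower at 9 days. Of 25 glycolysis and hypoxia genes, 11 fell and 0 rose (13 and 1 adjusted over the list alone; adjusted p = 2.16e-06, and adjusted p = 0.413 with an estimated correlation), with PFKP at -3.22 (adjusted p = 0.00485; -2.36 without untreated 1). In fatty acid synthesis 4 of 10 genes fell (6 adjusted over the list alone; adjusted p = 0.000195, and adjusted p = 0.413 with an estimated correlation), among them FASN (-1.10, adjusted p = 0.0136). In cholesterol synthesis 1 of 21 fell (8 adjusted over the list alone), and camera gave adjusted p = 0.00215, and adjusted p = 0.65 with an estimated correlation. Of 27 nuclear genes of oxidative phosphorylation 2 fell (12 adjusted over the list alone; adjusted p = 5e-05, and adjusted p = 0.413 with an estimated correlation), NDUFB10 (-0.81) and ATP5B (-0.69). Of 14 ER stress and amino acid response genes 3 fell (5 adjusted over the list alone; adjusted p = 0.000195, and adjusted p = 0.26 with an estimated correlation), ASNS (-2.08), TRIB3 (-1.53) and CHAC1 (-2.50; -1.82 without untreated 2).

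The 2 lists that camera called upward at 9 days were FOXO targets and the Notch receptors, ligands and processing machinery. Of 17 FOXO targets 4 rose and 0 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.26 with an estimated correlation), including PIK3IP1, a negative regulator of PI3K (2.02, adjusted p = 0.00209), and IRS2 (2.67, adjusted p = 0.00556). Of 23 Notch genes 2 rose and 0 fell (2 adjusted over the list alone; adjusted p = 0.0265, and adjusted p = 0.413 with an estimated correlation): the ligand JAG2 (1.54, SE 0.41, adjusted p = 0.0498; 2.28 without untreated 1) and the coactivator MAML1 (0.76, SE 0.20, adjusted p = 0.0498). NOTCH1 (0.94, SE 0.33, adjusted p = 0.118), NOTCH2 (-0.18, adjusted p = 0.684), NOTCH3 (0.12, adjusted p = 0.913) and JAG1 (1.30, adjusted p = 0.117) did not pass, and of 8 Notch target genes 0 passed by edgeR over all genes or over the list alone (HES1 -0.16, NRARP 0.33, HEY1 -0.69). HEY1 became -0.04 without untreated 1, -2.10 without 9-day 1 and 0.05 without 9-day 2. ERBB3 rose (0.78, SE 0.20, adjusted p = 0.0393), while ERBB2 stayed at 5632 ± 762 against 6159 ± 1840 CPM (-0.13, adjusted p = 0.801). EGFR, at 2 to 8 counts per library, was below the filter. CCND1 (-0.22, adjusted p = 0.639) and KDM5A (0.31, adjusted p = 0.373) did not pass. MYC rose (2.05, SE 0.22, adjusted p = 0.000992), as did the pro-apoptotic BMF (2.96, adjusted p = 0.003; 3.74 without untreated 1) and the efflux transporter ABCC5 (1.98, adjusted p = 0.00165).

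In the edgeR fit 361 genes were higher and 714 lower after 9 days (3354 at an unadjusted p under 0.05). Both counts were smaller without any 1 of the untreated and 9-day libraries. Such a fit leaves 1 sample in a group, and the fewer samples alone lower the counts. No call shared with the full fit changed direction. Of 57 named genes called, 21 were called whichever library was left out. Of those given above, MUC19 and ERBB3 lost their call without any 1 of the untreated and 9-day libraries, as did JAG2, MAML1, NDUFB10 and ATP5B, with adjusted p up to 0.128, 0.212, 0.211, 0.293, 0.313 and 0.402 in that order. All of these but MUC19 also lost it without long-term 2, JAG2 and MAML1 without long-term 1, and NDUFB10 and ATP5B without long-term 3. PCDH19 (adjusted p up to 0.251) and FASN (0.185) lost theirs without untreated 1, 9-day 1 or 9-day 2, CHAC1 (0.0787) without untreated 2 or 9-day 1, and IRS2 (0.0584) without untreated 1. The Notch list (adjusted p = 0.0555) and the FOXO list (0.0525) were not called without untreated 2, nor cholesterol synthesis (0.164) without untreated 1.

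**Figure D2:**
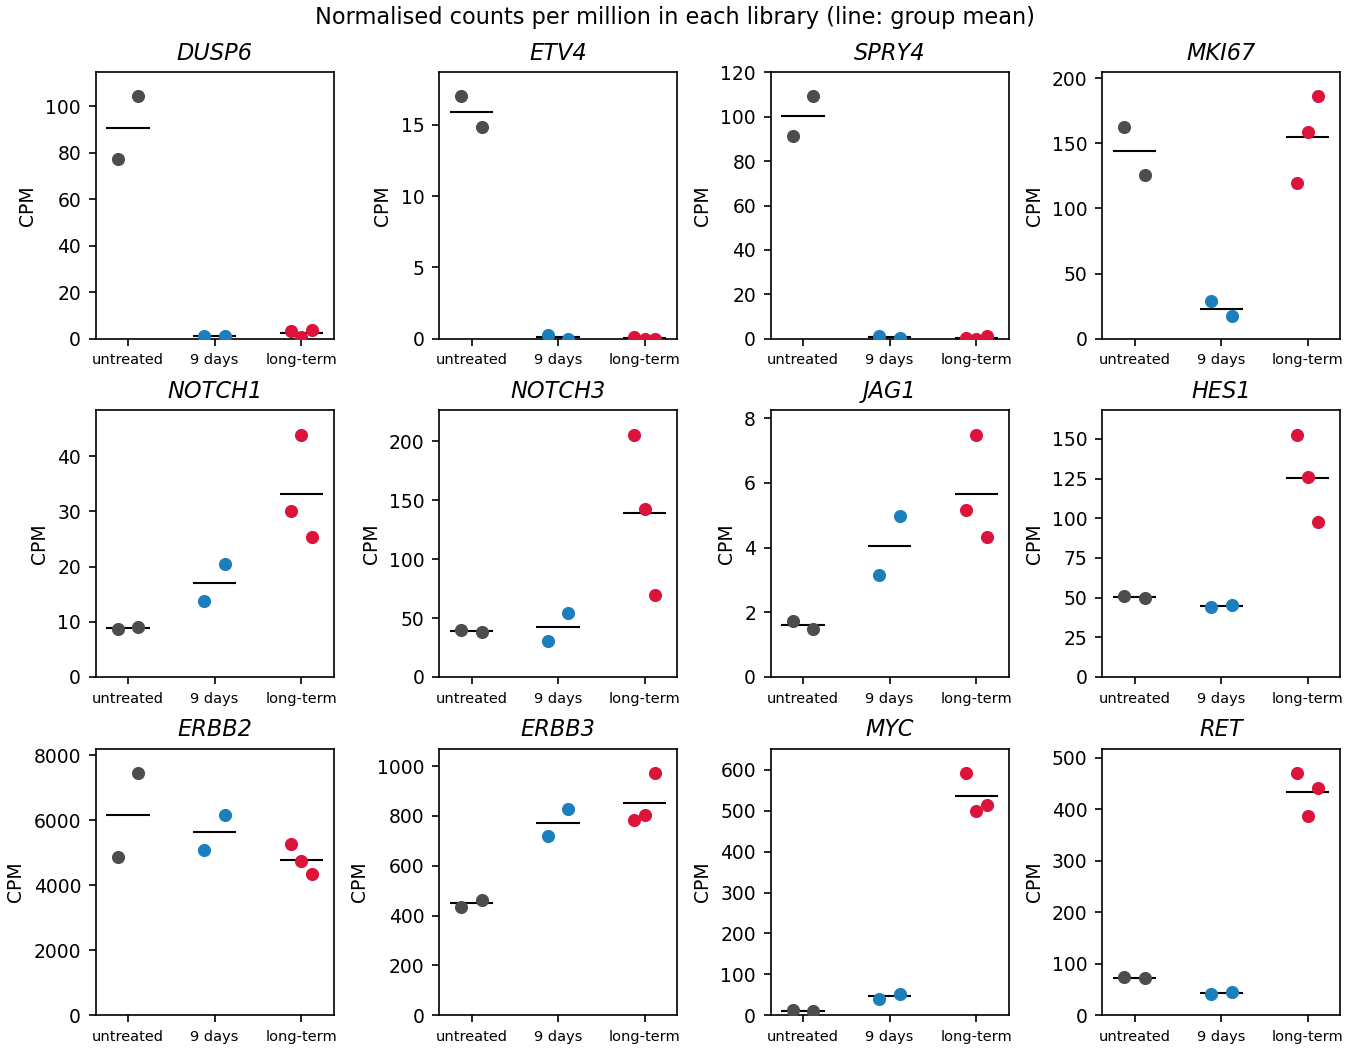
Normalised CPM (y axis, linear from 0) of 12 genes in each library, by group (x axis); points are libraries (n = 2, 2 and 3) and lines group means. DUSP6 falls from 90.8 CPM in untreated to 1.22 CPM at 9 days, and MKI67 is at 154.9 CPM in long-term libraries against 23.1 CPM at 9 days.

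In long-term lapatinib, DUSP6, SPRY4 and ETV5 were lower than in untreated cells, and MYC, NOTCH1, JAG2 and the receptor gene RET were higher. DUSP6 was at 2.72 ± 1.51 CPM (n = 3; log2 fold change -5.06, SE 0.40, adjusted p = 3.78e-05), SPRY4 at -7.61 (SE 0.60, adjusted p = 6.18e-05; -8.71 without long-term 3) and ETV5 at -7.51 (SE 0.59, adjusted p = 3.35e-05; -6.68 without long-term 1 and -8.11 without long-term 3). MYC rose from 11.0 ± 0.789 to 535 ± 50.5 CPM (5.60, SE 0.25, adjusted p = 1.03e-06). Of 23 Notch receptors, ligands and processing genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). Camera did not call the list (adjusted p = 0.253, and adjusted p = 0.819 with an estimated correlation). Fry called it upward here (adjusted p = 0.0424) but not at 9 days (adjusted p = 0.0524), the reverse of camera. NOTCH1 rose from 8.88 ± 0.335 to 33.1 ± 9.66 CPM (1.90, SE 0.32, adjusted p = 0.00189), and NOTCH3 from 39.0 ± 1.31 to 139 ± 68.2 CPM (1.84, SE 0.44, adjusted p = 0.0129). NOTCH3 was at 205.46 and 142.67 CPM in long-term 1 and 2, both with L1 titles. It was at 69.11 CPM in long-term 3, against 39.97 and 38.11 CPM in the untreated libraries. JAG1 rose by 1.79 (SE 0.44, adjusted p = 0.0107) and JAG2 by 2.08 (SE 0.40, adjusted p = 0.00349, and 2.76 without untreated 1).

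Of 8 Notch target genes 3 rose and 0 fell (3 adjusted over the list alone, camera adjusted p = 0.581). Over all 14472 genes 39.1% were called in this comparison, so 3 of 8 is not above the share over all genes. The 3 were HES1 (1.32, SE 0.23, adjusted p = 0.00206), HES2 (2.40, SE 0.34, adjusted p = 0.000832) and NRARP (0.66, SE 0.23, adjusted p = 0.0412). HEY1 (-2.08, SE 0.80, adjusted p = 0.0608) and NOTCH2 (-0.38, adjusted p = 0.145) did not pass. HEY1 was called lower without 9-day 1 (adjusted p = 0.0458), without 9-day 2 (0.0395), with no filter (0.0314) and with the replicate block (0.0412). NOTCH2 was called lower with the batch term (0.0424). Without untreated 1 HEY1 was at -1.49 (adjusted p = 0.377). NUMBL, named for its likeness to the Notch inhibitor NUMB, rose (2.34, adjusted p = 0.000794). The calls of NOTCH3 (adjusted p up to 0.108) and JAG1 (adjusted p up to 0.0637) were lost without untreated 1 and without untreated 2, and NRARP was not called in any of the 7 fits with a library left out (adjusted p up to 0.21, without untreated 2) or with the L1 libraries summed (0.0725).

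Among other receptor tyrosine kinases and ligands 8 of 17 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.166). RET rose from 73.1 ± 0.401 to 433 ± 42.4 CPM (2.57, SE 0.19, adjusted p = 2.81e-05) and FGFR4 by 1.43 (adjusted p = 0.00161), while EPHA2 (-6.10, adjusted p = 6.02e-05; -6.73 without long-term 3) and IGF2 (-3.94, adjusted p = 0.00189; -3.33 without long-term 1 and -4.96 without long-term 3) fell. ERBB3 rose (0.93, SE 0.18, adjusted p = 0.00395) and the ligand EREG fell (-2.61, adjusted p = 0.00239; -3.20 without long-term 1); of 7 ERBB genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.42). Fry called the ERBB list downward (adjusted p = 0.00383). ERBB2 did not pass (-0.36, SE 0.21, adjusted p = 0.195), nor did CCND1 (0.28, adjusted p = 0.324), KDM5A (-0.23, adjusted p = 0.315) or MKI67 (0.10, adjusted p = 0.783).

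Of 22 genes of the MYC and ribosome biogenesis list 10 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.000327, and adjusted p = 0.382 with an estimated correlation), with CAD at 1.82 and RRP12 at 1.43. The mitosis list stayed lower, with 22 of 27 genes down (25 adjusted over the list alone; adjusted p = 9.68e-08, and adjusted p = 0.819 with an estimated correlation), AURKA at -1.66 and CCNB1 at -1.32. Of 32 DNA replication genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.878 with an estimated correlation). Of 27 genes of oxidative phosphorylation 17 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 0.000498, and adjusted p = 0.819 with an estimated correlation). Of 15 ERK output genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.000397, and adjusted p = 0.325 with an estimated correlation). The 2 were EGR1 (4.75, adjusted p = 0.000169, and 5.38 without untreated 2) and PHLDA1 (1.31, adjusted p = 0.0101, and 1.16 and not called without untreated 2). The rule named both for long-term against 9 days, and for this comparison they were chosen after their values were seen. Camera did not call glycolysis (adjusted p = 0.253), fatty acid synthesis (0.348), cholesterol synthesis (0.938) or ER stress (0.42), nor FOXO targets (0.223). Fry called only the last of these, upward (adjusted p = 0.00105). The replication list was not called without long-term 1 (adjusted p = 0.0896) or long-term 3 (0.129), and without untreated 1 its direction turned (0.969).

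Luminal and stem cell genes moved both ways in long-term cells. Of 22 luminal genes 3 rose and 8 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.223). GATA3, a transcription factor of luminal cells, rose (2.02, adjusted p = 0.00119), and ELF5, a factor of the alveolar lineage, fell (-6.34, adjusted p = 8.17e-05). PIP had 2 counts over the long-term libraries and 154 over the untreated, a count ratio of 90.3 (interval 24.6 to 752). Its log2 fold change of -6.51 became -9.87 without long-term 3, -5.70 without long-term 1, -7.11 without untreated 1 and -5.55 without untreated 2. PIP was at 0 CPM in long-term 1 and 2, so the size without long-term 3 was not measured. Of 8 stem and progenitor genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with ALDH1A3 at -2.05 (adjusted p = 0.000529). Camera did not call this list (adjusted p = 0.494), while fry called it downward (adjusted p = 0.0247). Of 7 mesenchymal genes 2 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.699). CDH2, the neural cadherin, was at least 41.2-fold higher, and ITGA5 was 264 times lower by counts (interval 46.9 to 10500). The log2 fold change of ITGA5 (-7.80) became -10.18 without long-term 1. It was at 0 CPM in long-term 2 and 3, so the latter size was not measured. Of 12 basal genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.969).

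The highest fold changes in long-term cells were those of BAHCC1, at 0 counts in untreated libraries (at least 375-fold higher, adjusted p = 0.000587), SLIT1, the chemokine gene CXCL14 (10.89, SE 0.96, adjusted p = 0.000334) and SPTLC3 (at least 93.2-fold higher, adjusted p = 0.038). SPTLC3 was at 28.57 CPM in long-term 1 and at 2.68 and 1.96 CPM in long-term 2 and 3, and its log2 fold change of 10.08 became 7.84 without long-term 1. CXCL14, at 0 CPM in untreated 1 and 1.05 CPM in untreated 2, became 9.46 without untreated 1 and 16.19 without untreated 2. The latter is against a group at 0 counts, and its size was not measured. SLIT1 had 1 count in untreated libraries, a count ratio of 2770 (interval 496 to 109000). It was at 177.56 and 170.08 CPM in long-term 1 and 2 and at 35.93 CPM in long-term 3. The lowest were HIST1H4J (at least 658-fold lower), whose near-identical paralogs make its value uncertain, FAM5C (count ratio 1410, interval 253 to 55800), the calcium-binding protein gene S100A6 (at least 80.1-fold lower) and SDR16C5 (at least 62.9-fold lower). In the edgeR fit 2901 genes were higher and 2756 lower (7264 at an unadjusted p under 0.05). The log2 fold change of SLIT1 (11.01) became 13.51 without untreated 1, and that of FAM5C (-10.11) -12.50 without long-term 1. Both of these fits left the gene at 0 counts in a group. The log2 fold change of SDR16C5 (-9.85) became -8.95 without untreated 2. That of HIST1H4J (-12.84) became -12.01 without untreated 1 and -13.45 without untreated 2. SDR16C5 and HIST1H4J were at 0 counts in long-term cells. Sizes against a group at 0 counts were not measured. Without untreated 1 the counts were 1021 and 1169, and SPTLC3 lost its call without any 1 of the untreated and 9-day libraries (adjusted p up to 0.221).

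**Figure D3:**
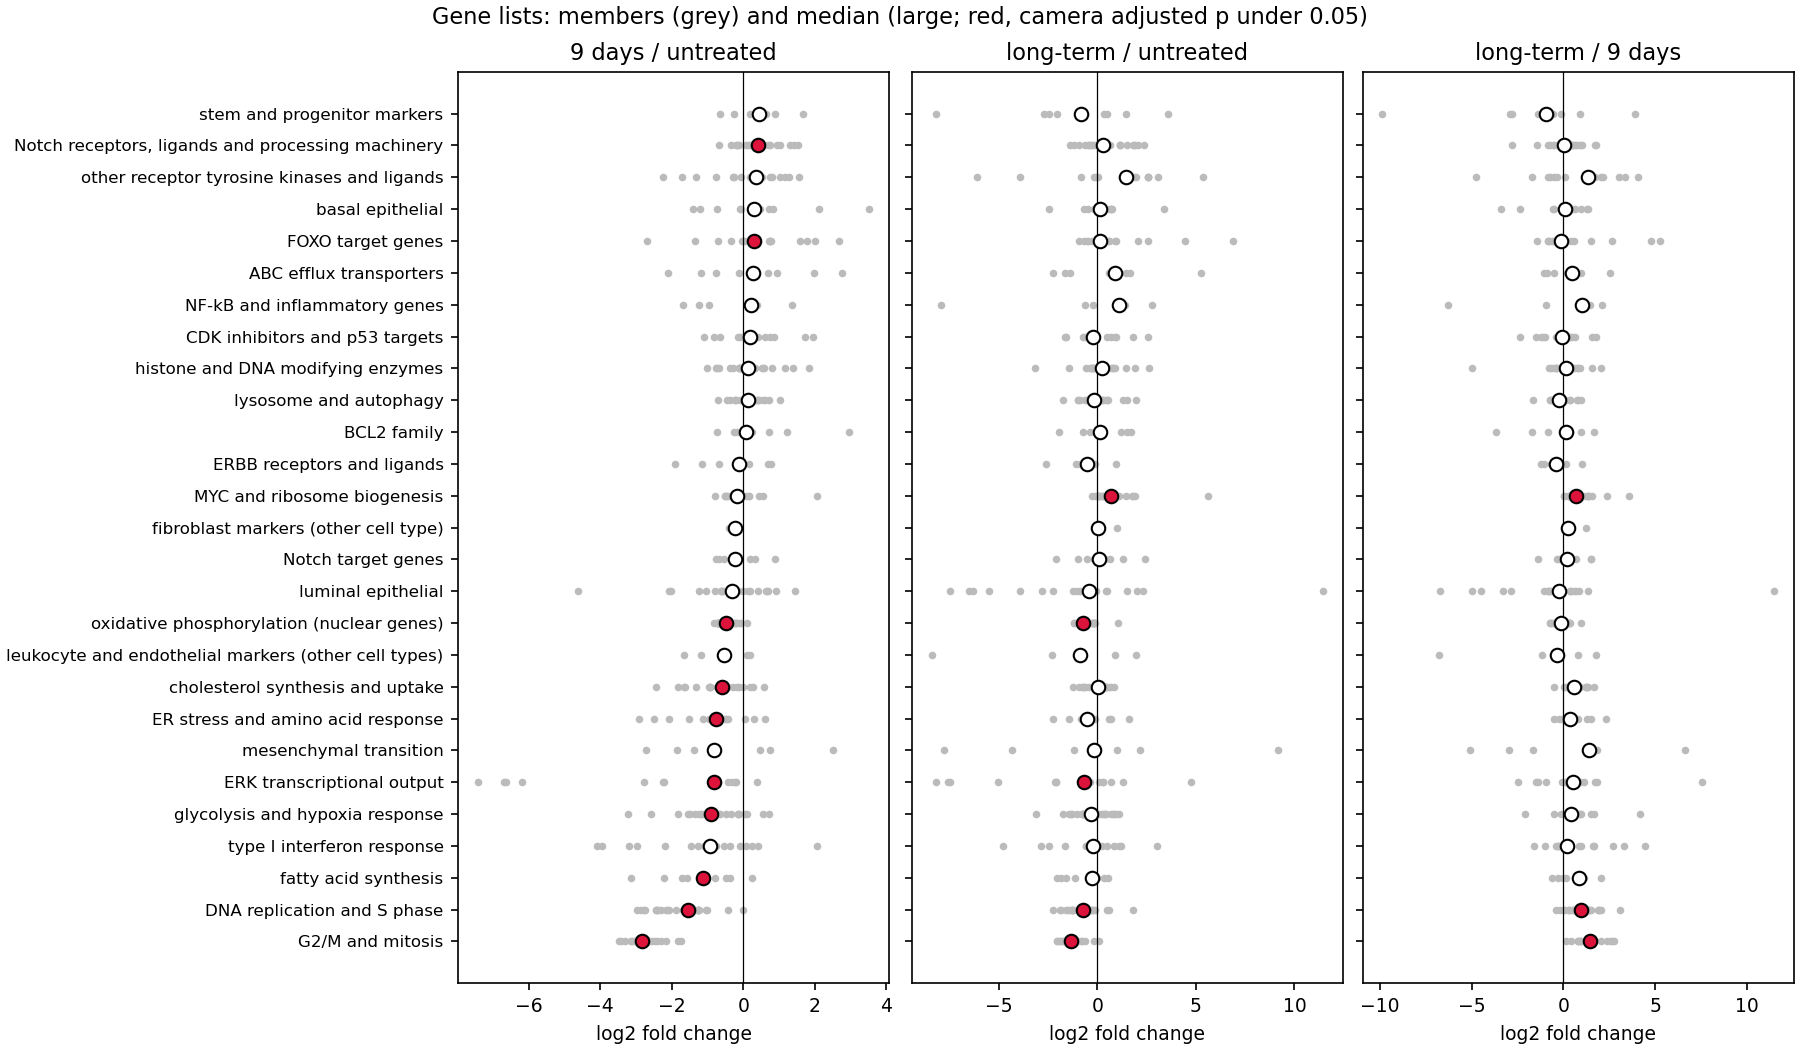
Log2 fold changes (x axis) of the members of 27 gene lists (y axis) in the 3 comparisons; grey points are genes, large points list medians, filled red where camera gave an adjusted p under 0.05. The mitosis median is -2.84 at 9 days and -1.36 in long-term cells against untreated, and 1.44 between long-term and 9 days.

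Set directly against 9 days, long-term cells had higher levels of cell division genes and MYC, while genes of the Notch list went both ways. Of the mitosis list 18 of 27 genes rose and 0 fell (22 adjusted over the list alone; adjusted p = 1.17e-10, and adjusted p = 0.783 with an estimated correlation), and MKI67 was 2.74 higher (SE 0.30, adjusted p = 0.00037). Of 32 DNA replication genes 12 rose and 0 fell (12 adjusted over the list alone; adjusted p = 0.000361, and adjusted p = 0.783 with an estimated correlation). Of 22 MYC and ribosome biogenesis genes 11 rose and 0 fell (13 adjusted over the list alone; adjusted p = 1.55e-06, and adjusted p = 0.379 with an estimated correlation), with MYC at 3.55 (SE 0.22, adjusted p = 1.46e-05). HES1 rose (1.49, SE 0.23, adjusted p = 0.00198), NOTCH1 rose (0.96, SE 0.30, adjusted p = 0.0412), NOTCH3 rose (1.72, SE 0.44, adjusted p = 0.0251) and the ligand DLL1 fell (-1.44, adjusted p = 0.0109). Of 23 Notch genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.999). JAG1 (0.49, adjusted p = 0.372), JAG2 (0.54, adjusted p = 0.281), NOTCH2 (-0.20, adjusted p = 0.473), HEY1 (-1.39, adjusted p = 0.213; 0.03 without 9-day 1 and -2.13 without 9-day 2), NRARP (0.34, adjusted p = 0.279), ERBB2 (-0.23, adjusted p = 0.44), ERBB3 (0.14, adjusted p = 0.58) and CCND1 (0.50, adjusted p = 0.117) did not pass, and KDM5A fell (-0.54, SE 0.18, adjusted p = 0.047).

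EGR1, an immediate early gene, rose from 0.797 ± 0.153 CPM at 9 days to 147.5 ± 55.0 CPM (7.53, SE 0.54, adjusted p = 5.09e-05). RET rose by 3.34 (SE 0.20, adjusted p = 1.46e-05). BMF (-3.68, adjusted p = 0.000225) and the CDK inhibitor CDKN2B (-2.36, adjusted p = 0.000653) fell. CXCL14 (10.03, SE 0.86) and SLIT1 (8.06, SE 0.94) were again among the highest, with VSTM2A (at least 119-fold) and TFCP2L1 (at least 83.1-fold). The lowest were HIST1H4J (at least 343-fold lower), ALDH1A1 (at least 80.4-fold), TLL1 (at least 52-fold) and FAM5C (count ratio 579, interval 104 to 22900). Without 9-day 1 and without 9-day 2 in turn, the log2 fold change of CXCL14 became 9.42 and 10.64, that of FAM5C (-8.79) -7.87 and -9.39, that of ALDH1A1 (-9.86) -7.95 and -10.53 and that of TLL1 (-9.24) -7.54 and -9.87. FAM5C became -11.18 without long-term 1, and VSTM2A (9.96) 9.27 without long-term 3. ALDH1A1 and TLL1 were at 0 CPM in long-term cells, FAM5C in long-term 2 and 3, and VSTM2A at 9 days. Sizes against a group at 0 were not measured. In the edgeR fit 1887 genes were higher and 1495 lower (5791 at an unadjusted p under 0.05). Without 9-day 1 the counts were 440 and 526, without 9-day 2 1172 were higher, and without long-term 2 929 were lower. Without 9-day 1 the calls of NOTCH1 (adjusted p = 0.312), NOTCH3 (0.189), KDM5A (0.245) and DLL1 (0.0663) were lost. NOTCH1, NOTCH3 and KDM5A also lost theirs without untreated 1, untreated 2 or long-term 2, NOTCH1 and KDM5A without long-term 1 or with the L1 libraries summed (adjusted p = 0.0825 and 0.0958) and NOTCH1 without 9-day 2, and the replication list was not called without 9-day 2 (adjusted p = 0.137).

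Across 14472 genes the log2 fold changes against untreated at 9 days and in long-term cells had Pearson r = 0.557, and genes are not independent replicates. Simulations of unchanged groups, with the untreated libraries simulated as well, gave r = 0.563, the median of 20. The observed correlation therefore did not exceed that from simulated shared controls. The simulations did not hold the measured untreated libraries fixed. The covariance was 0.697, against a median of 0.107 and at most 0.113 in the simulations, so it exceeded what the simulated shared controls gave. Of the calls, 239 genes were higher and 478 lower at both times, against 72 and 136 for independent lists of the same lengths. The simulated groups gave a median of 0 and 0 shared calls, which follows from their having almost no calls. The untreated libraries were not split between the comparisons, since each part would hold 1 library, and part of the sharing above 72 and 136 may come from the shared controls.

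The authors' deposited table lists 594 genes higher and 859 lower at 9 days, 3045 and 3175 in long-term cells, and 1814 and 1593 between long-term and 9 days, at adjusted p up to 0.1. Across symbols found once, log2 ratios of the means in the authors' deposited table and the fold changes here had r of 0.9974, 0.9974 and 0.9978 in the same order. The deposited table holds only genes called in at least 1 comparison. These r values therefore cover 6669, 6637 and 6651 selected genes with means above 0, and not all genes tested here. Of genes the authors' deposited table calls at adjusted p under 0.05, 69.5%, 89.6% and 85.5% were also called here in the same direction. Both come from the same libraries and are not independent.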

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

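The tests with thinned libraries and with a term for short RNAs, and the tests on short RNAs themselves, were chosen after the result was seen; leaving out each library was planned before. The genes and lists given here were picked out because their response at 9 days and in long-term lapatinib differed by a direct test between the 2 lapatinib groups.

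Lists of cell division and of growth stood apart between exposures: medians of the long-term against 9-day log2 fold changes were 1.44 for the mitosis list, 0.96 for DNA replication and 0.69 for MYC and ribosome biogenesis, none called with an estimated correlation. MKI67 was -2.64 against untreated at 9 days and 0.10 in long-term cells, a difference of 2.74 (adjusted p = 0.00037, edgeR). EGR1 went in opposite directions, -2.78 at 9 days (adjusted p = 0.0152) and 4.75 in long-term cells (adjusted p = 0.000169), a difference of 7.53; without untreated 2 these were -2.13 and 5.38, and its 9-day call was lost without 9-day 1 (adjusted p = 0.0924) or 9-day 2 (0.0843). RET did likewise, -0.77 and 2.57, a difference of 3.34; its 9-day call was lost without any 1 of the untreated and 9-day libraries, long-term 2 or long-term 3 (adjusted p up to 0.269). These were 2 of 32 genes called in opposite directions. HES1 differed by 1.49, NOTCH3 by 1.72 and NOTCH1 by 0.96, and KDM5A by -0.54; without 9-day 1 the calls of NOTCH3, NOTCH1 and KDM5A were lost (adjusted p = 0.189, 0.312 and 0.245), and without 9-day 2 that of DNA replication (0.137).

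More genes were called in long-term cells (5657) than at 9 days (1075). An additional long-term library is argued against, since the lowest count with 1 long-term library left out was 4287. Unequal depth is argued against, since with every library thinned to the shallowest the counts were 5030 and 935. A term for untreated 1 and 9-day 1, the libraries with most RNA from short genes under 140 nt, gave 4125 and 1584. The 9-day and long-term cells were both kept in 1 µM lapatinib. The length of exposure stays open as a biological explanation, but cannot be told apart from other differences between these groups, such as selection of cells. Time in culture without drug was not analysed here.

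Small nucleolar, Cajal body and nuclear RNAs differed between libraries of 1 group: the 67 such genes under 140 nt summed to 689.6 and 599.6 CPM in untreated 1 and 9-day 1, and to 258.7 to 426.6 CPM in the other 5 libraries, while the 12 of 180 nt or longer were lower in library 1 than in library 2 (1134.1 and 1932.7 CPM untreated, 1067.5 and 1267.6 CPM at 9 days) and all 101 summed highest in untreated 2 (2665.2 CPM). Depth cannot be told apart from other differences, since library 1 was the deeper of both numbered pairs, and its test was tried in 3 versions, the later 2 made after the value of the one before was seen. In the first, 9-day 2 had 0.785 times the pooled short RNA level of untreated 1 despite 1.26 times its total, which lay between the bounds set for and against depth (1 and 0.5); this did not exclude depth, while the later versions went against it, with median log2 ratios over 101 genes of -1.04 for that pair (interval -1.23 to -0.79) and -0.24 for long-term 1 over the shallower long-term 2 (interval -0.38 to -0.08). The second compares groups and the third rests on 1 pair, so neither settles it. The log2 ratio of library 1 over library 2 fell with transcript length, with Spearman rho across 93 genes of -0.621 in the untreated and -0.586 in the 9-day pair, which is consistent with a different loss of short fragments in library preparation; no biological explanation was tested.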

How the results depend on the processing

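The batch term, the 5-library subset and the thinning were chosen after seeing the data. Of 290 results for named genes, 155 kept their side of the threshold under all settings run, 133 lost a call and 2 (HEY1 and NOTCH2 in long-term cells) gained one under some setting, and none changed direction with a call. With single libraries left out, counts of genes for 9 days against untreated ranged from 70 to 531 higher and 197 to 768 lower, for long-term against untreated from 1021 to 2853 and 1169 to 2819, and for long-term against 9 days from 440 to 1755 and 526 to 1620. With 1 sample left in an arm, that sample is assumed to vary like the other groups. Genes higher at 9 days numbered 596 with no filter, 663 by DESeq2 and 571 with the replicate block or the batch term, against 361. In the 5 libraries without untreated 1 and 9-day 1 the counts were 41 and 131 at 9 days, 1064 and 1198 in long-term cells, and 479 and 451 between long-term and 9 days; the fewer samples alone lower such counts. The replicate numbers come from titles of 2 pairs only, which do not settle whether they pair the samples; differences between numbers 1 and 2 had r = 0.499 across genes in the untreated and 9-day pairs, and the block moved no other count past 1.5 times. With the L1 libraries summed into 1 sample, which also leaves fewer samples, genes called fell from 5657 to 4797 for long-term against untreated and from 3382 to 2474 for long-term against 9 days; 26 of the 290 named results lost a call, among them JAG2 (adjusted p = 0.0593), MAML1 (0.0642), NDUFB10 (0.051) and ATP5B (0.0529) at 9 days. Lists called at 9 days, in long-term cells and between them numbered 10, 5 and 3. With an estimated correlation they were 1, 0 and 0, with fry 8, 11 and 8, and for long-term against 9 days 5 with the batch term, 5 in the 5 libraries and 5 without 9-day 1. The replication list in long-term cells had adjusted p from 5.92e-09 without untreated 2 to 0.969 without untreated 1, where its direction turned, and it was not called with the batch term (0.456), in the 5 libraries (0.984) or thinned (0.0591). Of 702 genes the authors' deposited table calls at 9 days under adjusted p of 0.01, 39.9% also had an adjusted p under 0.01 here. Elsewhere the cause was not tested. Pseudocounts of 0.1 and 5, and a filter on low normalised values, were planned only for a table of normalised values and were not run, since the table holds counts.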

Other observations

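The tests on neighbouring genes were chosen after the result was seen, and the genes in the next paragraph were chosen after their values were seen.

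Beside ERBB2, the neighbouring genes PNMT, which makes adrenaline, and PPP1R1B fell. PNMT went from 333 ± 50.3 CPM in untreated to 38.6 ± 14.7 at 9 days (log2 fold change -3.11, adjusted p = 0.000652) and 0.863 ± 0.0862 in long-term cells (-8.55, adjusted p = 1.01e-06). PPP1R1B fell as well (-3.43 and -6.81). STARD3 did not pass (0.10 and -0.08), and GRB7 fell in long-term cells (-0.90, adjusted p = 0.00508). The serine synthesis genes PSAT1 (-4.19 and -2.12) and PHGDH (-4.56, not called without untreated 1, 9-day 1 or 9-day 2, adjusted p = 0.0825, 0.0914 and 0.114; and -3.06, or -3.65 without long-term 1, not called without untreated 1, adjusted p = 0.0509) and the cystine transporter gene SLC7A11 (-3.26 and -1.66) fell at both times. LIFR, a cytokine receptor gene, rose in long-term cells (3.10, adjusted p = 1.85e-05), as did TIMP3 (8.27, adjusted p = 3.16e-05) and PVT1, the non-coding gene next to MYC (2.24, adjusted p = 0.00017).

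Other lists held few called genes at 9 days or went both ways. Over all 14472 genes, 7.4% were called at 9 days and 39.1% in long-term cells. Members that rose and fell at 9 days were 1 and 0 of 15 for CDK inhibitors and p53 targets (2 and 0 adjusted over the list alone), 0 and 1 of 16 for interferon genes (0 and 1), 0 and 0 of 7 for NF-kB genes (0 and 1), 0 and 0 of 22 for lysosome genes (0 and 0), 1 and 0 of 11 for the BCL2 family (1 and 0), 1 and 1 of 8 for ABC transporters (3 and 3) and 2 and 1 of 25 for histone and DNA modifying enzymes (2 and 1). In long-term cells they were 4 and 1 for CDK inhibitors (4 and 1 over the list alone), 1 and 3 for interferon (1 and 1), 2 and 1 for NF-kB (2 and 1), 3 and 4 for lysosome (5 and 6), 3 and 1 for BCL2 (3 and 1), 4 and 3 for ABC transporters (4 and 3) and 6 and 3 for modifying enzymes (6 and 3). Camera called none of these 7 lists in either comparison. Fry called modifying enzymes upward at 9 days (adjusted p = 0.0215) and in long-term cells (0.00172). It also called ABC transporters upward in long-term cells (adjusted p = 0.0286), and none of the others. Of the 3 measured fibroblast markers none passed in any of the 3 comparisons by edgeR, over all genes or the list alone. Fry called the fibroblast list lower at 9 days (adjusted p = 0.00997) and higher in long-term cells (0.0207). Of 5 leukocyte and endothelial markers, 2 rose (LYZ 0.88, adjusted p up to 0.186 and lost without untreated 1, untreated 2, long-term 1 or long-term 3, and PECAM1 1.96, or 2.61 without untreated 2, adjusted p up to 0.254 and lost without untreated 1, long-term 1 or long-term 3) and 2 fell (CD68 -2.32, CDH5 at least 23.5-fold lower, with a log2 fold change of -8.42, or -9.01 without untreated 1 and -7.48 without untreated 2) in long-term cells (2 and 2 adjusted over the list alone).

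Over 314 blocks of 40 neighbouring genes, the variance of block medians of log2 fold change in long-term cells was 0.1145, against at most 0.0397 in 1000 shuffled gene orders. With 1 gene per symbol stem and block the variance was 0.0938, against at most 0.037. This step left families with short symbols, such as the ZNF genes, uncollapsed. It therefore cannot tell whether clusters of related genes account for the pattern. The lowest block, from GMNN to HIST1H2BK in the histone gene cluster, had a median of -1.25 with 30 genes called lower and 0 higher. The block from DNAAF1 to ANKRD11 had a median of 0.93 with 23 genes called higher and 0 lower, and the block from HRASLS2 to TM7SF2 a median of -1.10 with 24 called lower and 2 higher. A change in copy number may stay open as a hypothesis, since no DNA was analysed here; the pattern was present at 9 days as well, against the same untreated libraries (variance 0.0247 against at most 0.0137 in shuffled orders, and 0.0174 against at most 0.0138 with 1 gene per stem), and between long-term and 9-day cells, without the untreated libraries (0.074 against at most 0.0244, and 0.0658 against at most 0.0238).

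The abundant transcripts TVAS5 and BC018860 spanned 1.48-fold and 1.44-fold in raw counts across libraries whose totals spanned 4.35-fold. Their CPM was therefore not constant, from 10713.8 (9-day 1) to 31359.8 (long-term 3) for TVAS5 and from 2551.9 to 8511.2 in the same libraries for BC018860.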
